A study of Pinus pinaster with 6 samples.

How the data were processed

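Developing xylem, the layer of young wood cells next to the cambium, was compared between the crown and the base of the trunk of 3 field-grown maritime pines (Pinus pinaster) on 2-colour cDNA microarrays. Per the labels' protocols, total RNA was amplified and labelled by the amino allyl method, in which the dye is coupled after the RNA has been made. Crown and base RNA of one tree shared an array, and each tree had 2 technical replicate arrays, so the 6 arrays hold 3 biological replicates. Per the labels, tree 1 carried crown RNA in Cy5 and base RNA in Cy3, and trees 2 and 3 carried the opposite dyes. Trees 1 and 2 were harvested in 2005 and tree 3 in 2007.

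The deposited values are read as log2 ratios of both channels, with 1 value for each of 4224 probe IDs on each array and none missing. The file states no log base; log2 was taken because the submitters' processing notes list limma 2.14.5 and R 2.7.1, and limma gives 2-colour ratios as log2. Fold changes below rest on that base. Background correction, normalization within and between arrays, spot filters and the handling of duplicate spots are not given in the sources used here. The array medians of the deposited log2 ratios lay between -0.02 and 0.002, so the values were already centred. Single-channel intensities were not analysed here, so neither signal over background nor dependence of the ratio on brightness could be examined, and the number of arrays limits the precision.

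The labels do not say which way the ratio runs or whether the tree with swapped dyes had been turned. A rule for this was fixed before the data were examined, as were the test, the alternatives and the choice of named IDs. Tree 1 correlated positively with trees 2 and 3, above the bound of 0.1 set in the rule, so the ratios were read as already turned to a common direction and used with their deposited signs. The titles of all 6 arrays put crown first, whatever the dyes, which would make the direction crown over base if the titles describe the ratio. One feature of the values leaves this open: 99.5% and 99.3% of those of the tree 1 arrays carry more than 6 significant digits, against 0% on the other 4 arrays. The cause of this separate number format is not known. If tree 1 was the one that was turned, the common direction would be that of Cy5 over Cy3 in trees 2 and 3, which is base over crown. Ratios are therefore reported as positive or negative.

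Technical replicates were averaged within each tree (avearrays), and the mean ratio of the 3 trees was tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with two-sided p-values, Benjamini-Hochberg adjustment over all 4224 IDs and a threshold of 0.05. The tree is its own block in this test because crown and base share an array. No filter or recentring was applied. The test was run on 20 simulated sets of 4224 IDs for this comparison, with 200 changed IDs in each. The spread per ID was taken from the real fit, and technical noise of each tree's arrays was added to it. It recovered 86.0% of IDs changed by 0.5 and 99.95% of IDs changed by 1 on the log2 scale, with a mean of 5.78% false calls. Without any change, at most 9 IDs were called under either reading of the signs. The simulated IDs were independent and held no dye bias or plate shifts, so these counts do not bear on which reading is right.

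The IDs have the form of a plate number from 1 to 11 and a well of a 384-well plate, and every such well occurs once. The files do not pair IDs with genes, so the pathway and cell type lists drawn up beforehand, including those for photosynthetic tissue, phloem, dividing cells and resin ducts, could not be applied, and under the rule for named IDs only the 2 largest mean ratios per direction are named, among IDs past the threshold with 1 sign in all 3 trees. Plates were compared by reassigning IDs to plates 10000 times. The alternatives were the other reading of the signs, recentring, rescaling, all 6 arrays with the tree as a random block, a dye term, a minimum of 2 trees with values, a robust variance model, another threshold, a 1.5-fold minimum and each tree left out. Recentring by plate was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.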

Results

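Gene expression in developing xylem was compared between crown and base of the trunk in 3 maritime pines aged 28 to 31 years. Wood laid down within the crown is generally described as juvenile and that at the base of an adult trunk as mature. The data comprised 6 2-colour cDNA arrays, 2 for each tree, with 4224 probe IDs on each. The standard deviation of the log2 ratios over all IDs was 0.463 and 0.448 on the arrays of tree 1, 0.374 and 0.373 on those of tree 2, and 0.380 on both of tree 3. By the order in the titles, a positive ratio would be higher expression in crown xylem, but the labels do not settle this direction. If tree 1 was the one turned, a positive ratio would be higher expression in base xylem.

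The technical replicate arrays of a tree correlated with Pearson's r of 0.956, 0.937 and 0.962 in trees 1, 2 and 3, and Spearman's rho of 0.939, 0.865 and 0.910, across IDs. The median absolute difference between them was 0.066, 0.069 and 0.058 on the log2 scale. Differences above 1 occurred at 5 IDs in tree 1, with a maximum of 2.42, at 0 IDs in tree 2, where the maximum was 0.785, and at 2 IDs in tree 3. Between trees, the averaged ratios correlated with r of 0.663 for trees 1 and 2, 0.719 for trees 1 and 3, and 0.749 for trees 2 and 3. Spearman's rho was lower, at 0.440, 0.575 and 0.687. These correlations run across IDs, which are not independent replicates. The sign of the ratio was the same in all 3 trees for 2175 of the 4224 IDs (51.5%), where independent signs would give 25%.

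**Figure D1:**
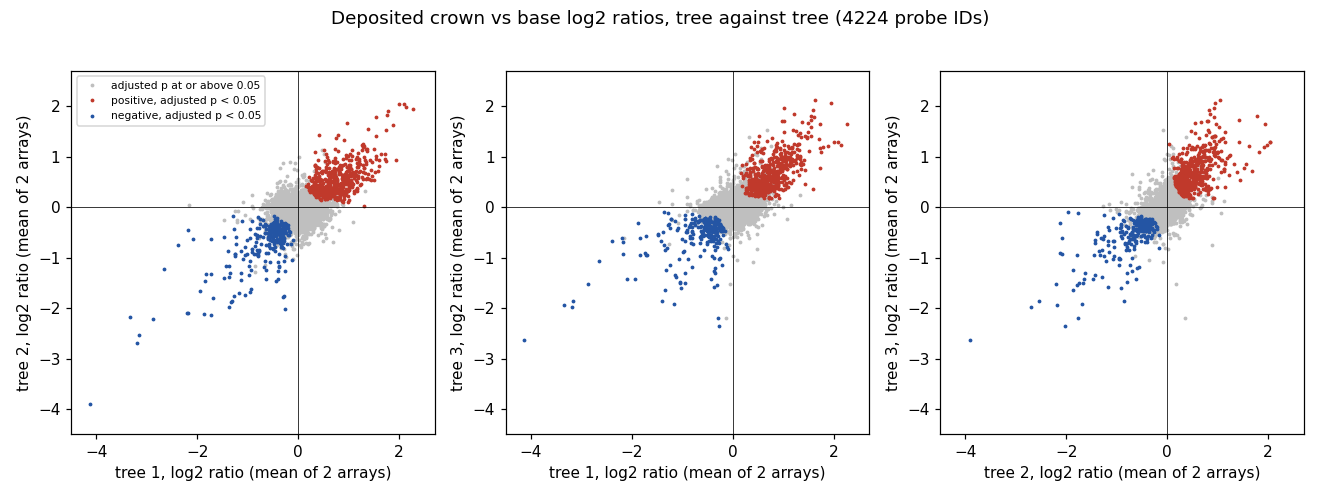
Each panel plots the log2 ratio of 1 tree against that of another (mean of 2 arrays per tree) for 4224 probe IDs. The 517 positive IDs (red) and 244 negative IDs (blue) past the adjusted p threshold of 0.05 lie in the quadrants of equal sign in every panel, and the lowest point is Q10L17, with -4.14 in tree 1, -3.90 in tree 2 and -2.63 in tree 3. The equal signs largely follow from selecting these IDs by a test on the same values.

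With the deposited signs read as already turned, the ratio of crown and base xylem differed from 0 at 761 of 4224 probe IDs (18.0%). With tree 1 turned against trees 2 and 3, as unturned dye ratios would require, 0 IDs passed (limma; 72 at an unadjusted p under 0.05), so a difference between the tissues rests on that reading. Of the 761, 517 had a positive ratio and 244 a negative one (limma, adjusted p under 0.05, n = 3 trees), and all 761 kept 1 sign on all 6 arrays. That equal sign largely follows from selecting the IDs by a test on these same values. Most differences were modest: the median size was 1.52-fold among positive and 1.44-fold among negative IDs. At least 2-fold differences were found at 65 positive and 45 negative IDs, and at least 4-fold differences at 0 positive and 5 negative IDs. The 4-fold count depended on the trees used: without tree 3 it was 4 positive and 7 negative IDs, without tree 2 it was 1 and 5, and with a dye term it was also 1 and 5. The smallest mean ratio past the threshold was 0.31 in size and the largest that missed it was 0.90, with a median standard error of 0.10 over all IDs. At an unadjusted p under 0.05 there were 1277 IDs. Without tree 1, the only one with crown RNA in Cy5, trees 2 and 3 gave 409 IDs, 377 of them among the 761 and with the same sign. Trees 1 and 2, both harvested in 2005, gave 600 IDs, of which 547 were shared, in a fit with 1 common variance for all IDs. Both fits reuse 2 of the 3 trees behind the 761, so much of the overlap is built in and is no replication. A dye term fitted beside the crown and base effect passed the threshold at 0 IDs (limma; 643 at an unadjusted p under 0.05), but dye order is confounded with tree 1 and harvest year with tree 3. The 643 exceed a share of 0.05 of the 4224 IDs. Both terms of this fit have the same standard error at each ID, and the crown and base effect passed at 908 IDs. Low power alone therefore does not account for the count of 0. Dye effects that are smaller or at few IDs could still have been missed. The count of 0 does not show that a dye effect is absent.

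The largest negative ratios were those of Q10L17 and Q2I1. Q10L17 had a mean log2 ratio of -3.56 ± 0.81 (SD, n = 3 trees), an 11.8-fold difference, with a standard error of 0.26 and an adjusted p of 0.0014 (limma). Q2I1 had a mean of -2.62 ± 0.61 (SD, n = 3 trees), a 6.14-fold difference (standard error 0.21, adjusted p = 0.0014, limma). Its ratio was -3.19 in tree 1, -2.70 in tree 2 and -1.97 in tree 3. The largest positive ratios were those of Q8L21 and Q11J4. Q8L21 had a mean of 1.95 ± 0.31 (SD, n = 3 trees), a 3.87-fold difference (standard error 0.13, adjusted p = 0.0014, limma), with 2.27, 1.94 and 1.64 in trees 1, 2 and 3. Q11J4 had a mean of 1.81 ± 0.44 (SD, n = 3 trees), a 3.51-fold difference (standard error 0.16, adjusted p = 0.0015, limma), with 2.09 and 2.04 in trees 1 and 2 and 1.30 in tree 3. The genes behind these IDs are not named here.

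Among all IDs past the threshold, the median positive log2 ratio was 0.72 in tree 1, 0.46 in tree 2 and 0.61 in tree 3. The median negative ratio was -0.51 in tree 1, -0.61 in tree 2 and -0.45 in tree 3.

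Differences were unevenly spread over the 11 plates of 384 IDs. Plate 8 had the highest share past the threshold, 26.3%, with 75 positive and 26 negative IDs, and plate 7 the lowest, 13.0%, with 26 positive and 24 negative IDs. Plates 4 and 5 were mostly positive, with 61 against 9 and 59 against 11 IDs, whereas plate 10 had 28 positive and 31 negative IDs. Both the number past the threshold and the positive share varied more than under random reassignment of IDs to plates (permutation test, one-sided, p = 1e-04 for each, adjusted p = 1e-04 over 4 plate tests, the smallest p that 10000 reassignments can give). The test treats IDs as independent, which clones of one transcript are not. After each plate was recentred on its median, the share past the threshold still ran from 11.5% on plate 2 to 22.9% on plate 8 (permutation p = 3e-04, adjusted 6e-04 over 2 tests). The positive share then ran from 52.7% on plate 10 to 84.4% on plate 4 (permutation p = 0.0013, adjusted 0.0013).

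The plate medians themselves moved with the tree. On plate 3 the median log2 ratio was 0.11 in tree 1 but -0.13 in tree 2 and -0.09 in tree 3, and on plate 1 it was -0.13 in tree 1 but 0.09 and 0.05 in the other two. Over the plates, the difference between tree 1 and the mean of trees 2 and 3 had a standard deviation of 0.125, against a median of 0.021 and a maximum of 0.042 under random reassignment (permutation test, one-sided, p = 1e-04). The difference between trees 2 and 3 had a standard deviation of 0.041, against a random median of 0.013 (permutation p = 1e-04).

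**Figure D2:**
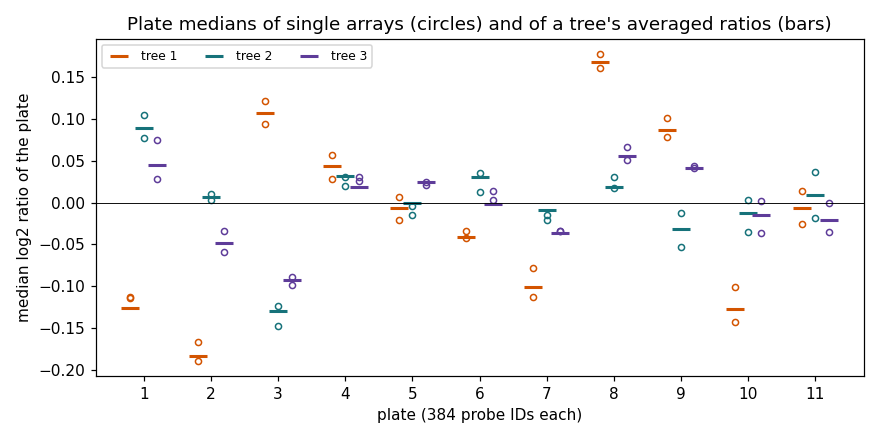
The median log2 ratio (vertical axis) is shown for each of 11 plates (horizontal axis), with circles for single arrays and bars for the averaged ratios of a tree. Tree 1 lies apart from trees 2 and 3 on several plates, such as plate 3, where it is at 0.11 and the other two at -0.13 and -0.09.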

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

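Reading the signs the other way, with tree 1 turned against trees 2 and 3, left 0 IDs past the threshold, 0 positive and 0 negative (limma), and 72 at an unadjusted p under 0.05. The mean correlation between trees was then -0.21, against 0.71 with the deposited signs, where Spearman's rho in place of Pearson's r gave a mean of 0.57. The mean of -0.21 joins 2 correlations of tree 1 that turning made negative with the unchanged 0.749 of trees 2 and 3. The signs were chosen by the correlation of tree 1 with trees 2 and 3, so the count rests on that choice. Requiring at least 1.5-fold left 375 IDs, 268 positive and 107 negative, by construction a subset. Leaving out 1 tree gave 409 to 771 IDs, 265 to 570 positive and 144 to 204 negative. The lowest total came without tree 1, and the cause was not tested. Without tree 2 or 3 the fit used 1 common variance for all IDs, so these 2-tree fits are not comparable in strength. The other settings stayed within 1.5 times of the main counts, from 709 IDs with plates recentred, a setting chosen after seeing the data, to 1011 at an adjusted p under 0.1. No setting gave an ID of the 761 the opposite sign past the threshold. With the dye term, 908 IDs passed for crown and base, and the term itself gave 0 IDs (limma). At an unadjusted p under 0.05 these counts were 1644 and 643. Smaller dye effects could still have been missed. Requiring values in 2 trees changed nothing because none was missing. The 4 named IDs kept sign and threshold side in 12 of 13 settings. In the other reading the choice of sign is arbitrary (limma adjusted p 0.998). The gene list tests were not run for want of gene names. Turning each tree in turn makes 4 patterns of signs with the real one, 1 of which (the real one) gave as many as 761 IDs, and the highest other gave 0 (limma; 8 to 72 at an unadjusted p under 0.05). A total of 4 splits is too few for a share under 0.05. Because the trees correlate, turning 1 of them puts their shared part into the spread between trees. The turned patterns were therefore bound to give few IDs and are no measure of chance.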

Other observations

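The tests on the common sign, on the plates, on the sizes and on the shift that equalises the calls were chosen after the result had been seen, except the counts after recentring of arrays or plates, whose bounds were set before those counts were known.

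Among the 5 IDs with a negative ratio of at least 4-fold, all 5 had the largest size in tree 1 and the smallest in tree 3. That order held for 67 of the 244 negative IDs (27.5%) and for 101 of the 517 positive IDs (19.5%). Over the mean of the trees, the median size of negative differences minus that of positive ones was -0.071 on the log2 scale (permutation test, two-sided, p = 0.0072, IDs taken as independent). After each array was recentred it was -0.061. Sizes depend on where 0 lies, which the p-value does not cover. A downward shift of all ratios by 0.08, left open below, would enlarge negative sizes and shrink positive ones. The direction of the size difference was not general: in tree 2 the negative median was the larger, -0.61 against 0.46, and in trees 1 and 3 the positive one was, 0.72 against -0.51 and 0.61 against -0.45. Whether the 5 IDs are clones of one transcript was not tested, since no sequences were used here.

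Tree 1 shared its signs with trees 2 and 3 although its dyes were swapped. A first explanation is that the ratios had been turned to one direction before deposit. A second is unturned dye ratios with a dye bias common to all arrays, in which case the 761 IDs would mark dye effects and not crown and base. Under the second, trees 2 and 3 should covary more than tree 1 does with them, and their covariance was lower by this measure, with a difference of -0.0123 (95% bootstrap interval over IDs -0.0182 to -0.0070). On the correlation scale the difference had the opposite sign, 0.058 (0.034 to 0.081), because the ratios of tree 1 were more widely spread. Turned ratios with a dye bias could also make trees 2 and 3 covary more, so neither scale can decide. The bootstrap over IDs does not cover the spread between trees. Both explanations therefore remain open. No array hybridised one RNA against itself. Single-channel intensities, which could show whether the signs were turned, were not analysed here. The second explanation would need a dye effect of -3.70 on the log2 scale at Q10L17, the mean over the 2 dye orders. The cause of the separate number format of tree 1 is not known, so it does not decide between them.

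The plate medians of tree 1 parted from those of trees 2 and 3. The permutation p of 1e-04 argues against random placement of IDs on plates free of plate-wide shifts. It does not argue against random placement itself, since plate-wide shifts on randomly placed IDs could give the same p. The spread over plates was 3.08 times as large between trees with opposite dyes as between trees with like dyes. Random reassignment of IDs to plates gave a median ratio of 1.71, with 95% of ratios between 0.90 and 3.24 (permutation test, one-sided, p = 0.035). Reassignment removes plate effects from every tree, although plate medians also differed between trees 2 and 3. It therefore does not give the ratio that plate effects unrelated to the dyes would produce. A plate-wide bias tied to the dyes predicts a raised ratio, but tree 1 is also a different tree with a separate number format, and these cannot be told apart with 1 tree of that dye order. Recentring every plate kept 672 of the 761 IDs (88.3%) past the threshold with the same sign. This lies between the bounds set beforehand, under 50% for plate shifts as the main source and at least 90% for none, so most calls did not need the plate shifts and a dependence of the remaining ones stays open.

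Of the IDs past the threshold, 67.9% were positive. Off-centre array medians are argued against: the medians lay between -0.018 and 0.002, whereas a downward shift of all ratios by 0.08 was needed before positive IDs (393) no longer outnumbered negative ones (414), and recentring each array left 69.2% positive. Centring by the authors off the unchanged genes, by that 0.08, stays open, because the IDs of unchanged genes are not known. An unequal makeup of the clone collection and a real asymmetry between crown and base xylem also stay open and were not tested.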
